A study of Mus musculus with 9 samples.

How the data were processed

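RNA from the whole lung of 9 mice was labelled with the dye Cy3 and hybridised to 9 one-colour Agilent expression arrays, 1 array per lung. The mice formed 3 groups of 3. Control lungs came from TRF1flox/flox mice without the cre transgene, collected at 11 months of age after 9 months of tamoxifen, and SPC-cre TRF1flox/flox lungs were collected at 5 months of age after 3 months of tamoxifen or at 11 months of age after 9 months of tamoxifen. The labels call the replicates of a group biological replicates, and no array was left out.

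The scanner files hold signal intensity per spot, per the file headers from Agilent Feature Extraction 10.7.3.1: a processed signal from which the software subtracted background within each array, the median pixel signal, the local background, and flags for dim, saturated and irregular spots. The processed intensity is not scaled between arrays. A separate deposited set of values holds 1 intensity per probe and array on a linear scale. There the authors had brought all arrays to nearly the same distribution, with medians of 163.3 to 164.1 and a common maximum of 413500. These values followed the median pixel signal of the same array across probes (log2 r = 0.9997 to 1) more closely than the processed signal. The tool behind that step is not given in the sources used here. They served as an alternative, and the scanner files were the main source because they carry the flags and the background.

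Each array held 62976 spots, of which 59305 were not control spots, for 56605 distinct probes. The log2 processed signal was expressed relative to the 75th percentile of the non-control probes of the same array. Spots marked as irregular were left out and the remaining spots of a probe were averaged. A probe was kept when it was well above background on every array of at least 1 group, which left 37647 probes. Probes were matched to gene symbols through RefSeq transcript identifiers. This named 32994 probes, and the other 23611 were counted but not tested as genes. For a gene with several probes the probe with the highest mean over all arrays was taken, a choice made without reference to the groups. The resulting table had 16843 genes, 11 of which lacked a value on at least 1 array. Gene positions came from the reference annotation of the GRCm38 assembly. The position of a probe within its transcript was not given in the sources used here, and sequences shared between close relatives, such as the Cd200r and Speer families, cannot be assigned to 1 member.

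All groups were fitted together in limma 3.58.1 under R 4.3.3, with group means as the only terms and 6 residual degrees of freedom, and files were read with the data.table package, version 1.17.8. The 3 contrasts were 9-month cre against 9-month control, 3-month cre against 9-month control, and 9-month cre against 3-month cre. Tests were two-sided moderated tests, and p-values were adjusted by the Benjamini-Hochberg method over the 16843 genes within a contrast. A gene was called, and is said to have risen or fallen, at an adjusted p under 0.05. Errors are standard errors (SE) of the fitted log2 fold change unless an SD is named, each from 3 arrays per group. Where every array of a group was below the well-above-background limit for a gene, the fold is given as a lower bound, with signals below the dimmest signal the software called well above background on an array raised to that level. No fold is given where that bound was not exceeded.

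The groups, contrasts, tests, 37 gene lists and the rule for naming genes were fixed before the data were examined. The lists cover telomere components, lung epithelial, stromal, endothelial and immune cell markers, damage, repair and inflammatory pathways, tissues that can be carried over at dissection, and markers of animal sex, time of day and tissue handling. They were tested with camera in limma at a preset correlation between genes of 0.01, adjusted over the 37 lists within a contrast, and again with the correlation estimated from the arrays. A rotation test, fry, was run beside it. The named genes are Terf1 and Sftpc in every contrast, then the 10 largest rises and the 10 largest falls among called genes whose arrays did not overlap between the groups, leaving out names that are clone, predicted or numbered identifiers. From each list up to 4 called members with the largest change were named, or up to 2 members given as values where none was called. Some genes taken in by the rule are not reported here. The count of called members is given over all genes and adjusted over the list alone.

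The array headers name 2 slides. Each was scanned in 1 session, and their arrays are listed under Results. The sex of each animal is not in the labels and was read from Xist and Y-linked probes. Alternatives recomputed each result with normexp background correction with an offset of 50 (on the median signal, since a mean signal was not used here), quantile normalization, scaling to the array median, the deposited values, no filter on dim probes, a filter on all 9 arrays, the mean of a gene's probes, only the 2 groups compared, an intensity trend with robust variance, array weights, the replicate number as a block, the slide as a block, animal sex as a covariate, and without each array in turn. Fits with slide and sex together, within slide 1, within slide 2 and without the sex-linked genes were added after seeing the data. A block for the scan session equals the slide block and was not run separately.

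The test was checked on simulated data in which 200 genes were changed in the 9-month cre against control layout. It called 66 of 100 genes changed by 2-fold and 89 of 100 changed by 4-fold, with 6 false calls among 161 (3.73%), and 0 of 20 lists of unchanged genes were called. The simulated values varied independently between genes, with no slide or sex effect. These rates therefore do not show how the tests behave where genes vary together or where slide or sex differ. For arrays, the number of replicates limits the precision, and signals near background compress fold changes.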

Results

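Gene expression was measured in whole lungs of 9 mice carrying floxed alleles of Terf1, the gene of TRF1, a shelterin protein that binds double-stranded telomere repeats. In 6 of them TRF1 could be deleted by a cre recombinase driven by the promoter of surfactant protein C (SPC, encoded by Sftpc). SPC is made by alveolar type 2 cells, which produce surfactant and renew the alveolar epithelium. All mice received tamoxifen, the drug that activates an inducible cre, at 250 mg/kg per week from 8 weeks of age. Littermates without cre, collected after 9 months of tamoxifen at 11 months of age, served as controls (n = 3). Lungs with cre were collected after 3 months of tamoxifen at 5 months of age (3-month cre, n = 3) or after 9 months at 11 months of age (9-month cre, n = 3). The 75th percentile of processed signal ranged from 1347 to 2002 intensity units over the 9 arrays, against a median local background of 28 to 35 units. No spot was saturated, with a count of 0 on each array.

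The groups also differed in features that the labels do not give. Slide 1 carried the 3 controls and 3-month cre replicate 1, and slide 2 carried 3-month cre replicates 2 and 3 and all 9-month cre arrays. On slide 1, 64.4% to 66.45% of probes were well above background, and on slide 2 the range was 69.39% to 73.66%. Xist, the RNA that silences 1 X chromosome in female cells, was at log2 levels of -7.40, -7.72 and -7.91 relative to the array 75th percentile in the controls and at -1.33 and -0.95 in 3-month cre replicates 1 and 3. It was at -0.99 and -0.71 in 9-month cre replicates 2 and 3. Y-linked transcripts showed the opposite pattern, so that all 3 controls read as male, and the cre groups read as 1 male and 2 females each. The first 2 principal components held 35.74% and 20.47% of the variance between arrays.

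Terf1 (GRCm38 chromosome 1, 15805546 to 15844052) was measured by 1 probe whose place relative to the floxed sequence is not given in the sources used here. Its mean level relative to the array 75th percentile was -0.07 ± 0.28 (SD, n = 3) in controls, -0.63 ± 0.05 in 3-month cre lungs and -0.59 ± 0.33 in 9-month cre lungs. The log2 fold change against controls was -0.52 ± 0.19 (SE) at 9 months (adjusted p = 0.131) and -0.55 ± 0.19 at 3 months (adjusted p = 0.190), and neither was called. The difference between the cre groups was 0.036 ± 0.19 (adjusted p = 0.921). With the slide as a block the Terf1 values against controls were -0.44 at 9 months and -0.50 at 3 months. Sftpc (chromosome 14, 70520941 to 70524081), the gene whose promoter drives cre, was 0.34 ± 0.16 higher on the log2 scale at 9 months (adjusted p = 0.222) and 0.14 ± 0.16 at 3 months (adjusted p = 0.685), which is not a call in either comparison. The array levels of Sftpc ranged from 7.89 to 8.60. Of the 20 measured telomere and shelterin components, 1 rose at 9 months, Wrap53, a telomerase trafficking factor, by 0.62 ± 0.13, and the list median was -0.022 (adjusted p = 0.733).

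**Figure D1:**
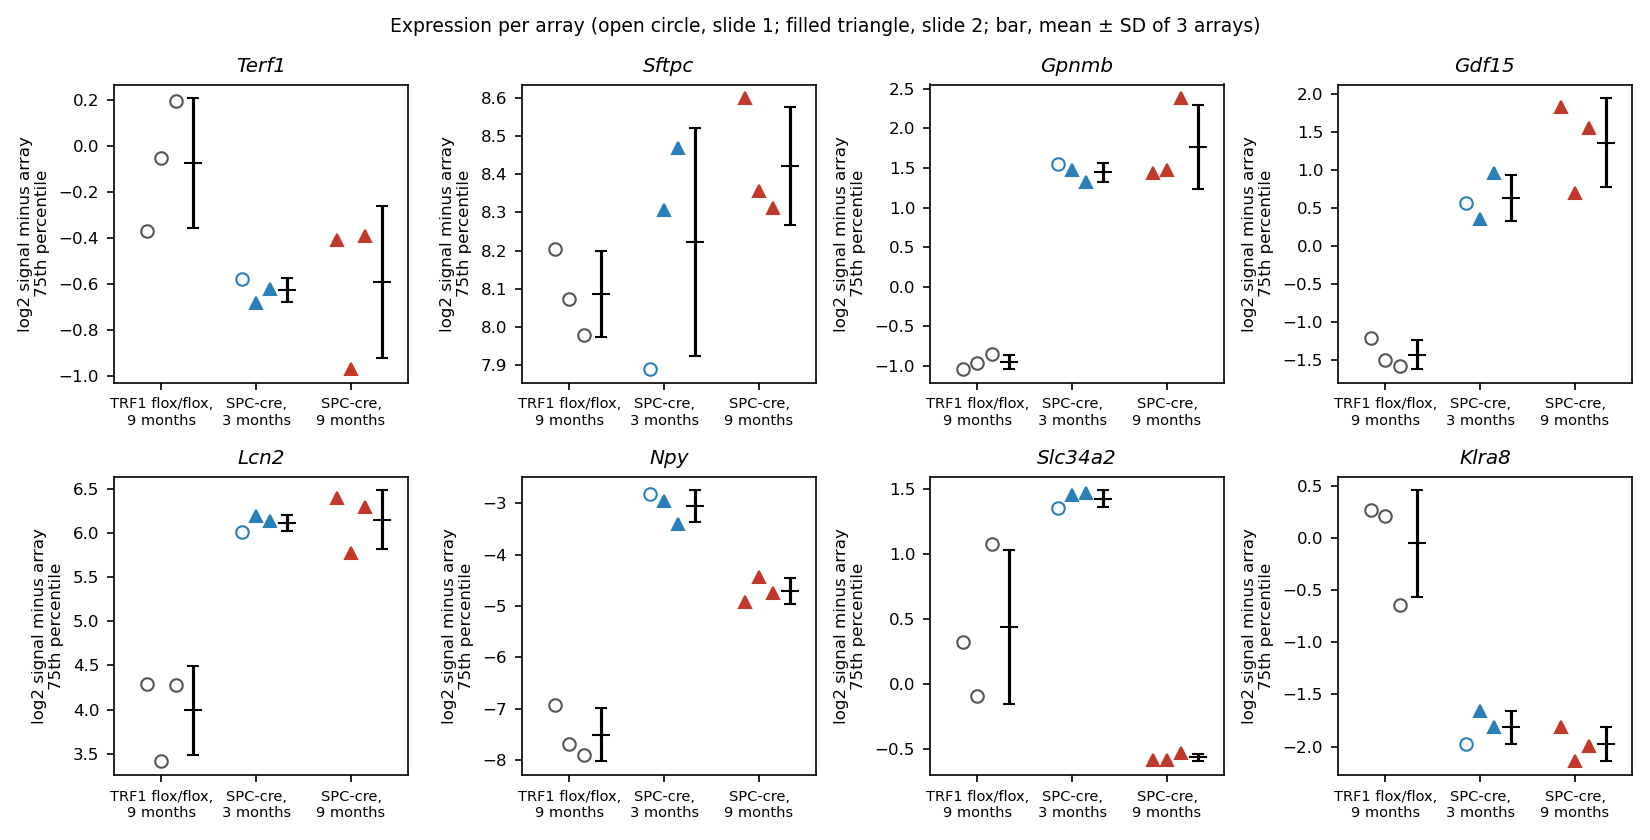
Log2 signal of 8 genes on each of the 9 arrays, relative to the array 75th percentile (y axis), by group (x axis), with open circles for slide 1, filled triangles for slide 2 and bars for the mean ± SD of 3 arrays. Gpnmb sat between -1.03 and -0.85 on the control arrays and between 1.32 and 2.38 on the cre arrays, while Terf1 ranged from -0.97 to 0.20 with overlapping groups.

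The comparison of 9-month cre with control lungs asked which genes differed at the late collection, at equal age and tamoxifen exposure. Markers of monocytes and interstitial macrophages were higher as a group, and 6 of 21 measured members rose and 0 fell, with a median log2 fold change of 0.91 (adjusted p = 1.79e-06, and adjusted p = 0.608 with an estimated correlation). Gpnmb, a lysosomal glycoprotein of lipid-laden macrophages, rose by 2.71 ± 0.24 (SE, n = 3 against 3), Trem2, a lipid-sensing receptor, by 2.39 ± 0.28 and Ms4a7 by 1.75 ± 0.42. Neutrophil markers had a median of 1.82, and 4 of 15 rose (adjusted p = 6.17e-05, and adjusted p = 0.654 with an estimated correlation). Among them Ngp, a granule protein, was at least 21.2-fold higher, Camp, the precursor of an antimicrobial peptide, rose by 4.91 ± 0.79, Mpo, the peroxidase of primary granules, by 2.58 ± 0.44 and Lcn2, an iron-sequestering protein also made by injured epithelium, by 2.16 ± 0.26. In the list of inflammatory chemokines and cytokines 5 of 28 members rose, with a median of 1.73 (adjusted p = 5.0e-05, and adjusted p = 0.713 with an estimated correlation). They included the neutrophil attractants Cxcl5 (3.26 ± 0.79) and Cxcl1 (2.24 ± 0.54), the cytokine Osm (2.17 ± 0.31) and Ccl9 (1.60 ± 0.32). Heart muscle genes, which a piece of vessel or atrium can carry into a lung sample, were lower in the same lungs, with a list median of -0.87 (adjusted p = 0.00338, and adjusted p = 0.732 with an estimated correlation), and 1 of 15 fell, Myh7, by 1.55 ± 0.31.

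Of 25 senescence and secretory phenotype genes 7 rose and 0 fell, with a median of 1.31 (adjusted p = 9.7e-05, and adjusted p = 0.621 with an estimated correlation). This list shares Il6, Il1b, Cxcl1, Cxcl2, Ccl2 and Ccl7 with the chemokine list and Gpnmb and Mmp12 with the macrophage list. Its rise is therefore not independent of theirs. Gdf15, a stress-induced cytokine, rose by 2.78 ± 0.29 and Cdkn1a, the cyclin-dependent kinase inhibitor p21, by 2.08 ± 0.32. Gdf15 and Cdkn1a are also p53 targets, and in that list 5 of 26 rose, with a median of 0.36 (adjusted p = 0.00338, and adjusted p = 0.529 with an estimated correlation). Among the others Pmaip1, a pro-apoptotic BCL2 relative, rose by 0.95 ± 0.14 and the death receptor Fas by 0.75 ± 0.18. Other probes of these genes stood at 0.80 for Cdkn1a and 0.064 for Fas, and neither was called. Genes of the transitional alveolar epithelium, a state described between alveolar type 2 and type 1 cells, had a median of 0.32 (adjusted p = 0.00732, and adjusted p = 0.608 with an estimated correlation). Of 17 members 4 rose, Lcn2, Cdkn1a, Lgals3 (1.00 ± 0.13) and Plaur (0.64 ± 0.14). Lcn2 and Lgals3 are also abundant in neutrophils and macrophages. Of 26 interferon response genes 3 rose, Oas2 by 1.71 ± 0.18, Oas1a by 1.49 ± 0.24 and Irf7 by 0.77 ± 0.16, with a list median of 0.32 (adjusted p = 0.0293, and adjusted p = 0.733 with an estimated correlation). A further Irf7 probe stood at 0.32. The 29 proliferation genes all had positive values, with a median of 0.93 (adjusted p = 0.00315, and adjusted p = 0.733 with an estimated correlation), but 0 were called in limma, with 2 at unadjusted p under 0.05. Mki67 was at 1.28 ± 0.58 and Ccna2 at 1.27 ± 0.62. Immediate early genes, which respond to tissue handling, had a median of 0.58 in the same lungs (adjusted p = 0.0293, and adjusted p = 0.713 with an estimated correlation), with 0 of 18 called in limma and 5 at unadjusted p under 0.05.

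All 18 resident fibroblast markers had negative values, with a median of -0.60 (adjusted p = 9.7e-05, and adjusted p = 0.529 with an estimated correlation). Of these 4 fell, Npnt, an alveolar matrix ligand, by 1.23 ± 0.26, Fgf10, a growth factor for lung epithelium, by 0.94 ± 0.16, Meox2 by 0.81 ± 0.18 and Col13a1 by 0.80 ± 0.16. A further Fgf10 probe stood at 0.11 and was not called. Smooth muscle and pericyte markers had a median of -0.59 (adjusted p = 0.00386, and adjusted p = 0.621 with an estimated correlation), with 0 of 14 called in limma and 5 at unadjusted p under 0.05. Synm was at -0.98 ± 0.26 and Hhip at -0.96 ± 0.24. Alveolar type 1 markers had a median of -0.39 (adjusted p = 0.0467, and adjusted p = 0.713 with an estimated correlation), with 0 of 15 called in limma, and 5 lower and 1 higher at unadjusted p under 0.05. Akap5 was at -0.92 ± 0.25 and Col4a3 at -0.91 ± 0.43. Within the fibrosis and extracellular matrix list 3 of 34 members rose, including Spp1 (1.82 ± 0.31) and Timp1 (1.31 ± 0.29), and the list itself was not called, with a median of 0.15 (adjusted p = 0.586). Alveolar type 2 markers had a median of -0.35 and were not called (adjusted p = 0.0866), but were called with the slide block (-0.27, adjusted p = 0.00143), quantile normalization (-0.44, adjusted p = 0.015) and the deposited values (-0.49, adjusted p = 0.0157). Of their genes S100g fell by 0.97 ± 0.23 and Etv5, a transcription factor of these cells, by 0.87 ± 0.16.

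The rule for named genes also took in rises of Saa3, an acute-phase protein (4.42 ± 0.72), Oosp1 (4.37 ± 0.79), Fgg, the fibrinogen gamma chain (4.35 ± 0.79), and Gpr84, a myeloid fatty acid receptor (3.93 ± 0.85). Prg2, the eosinophil granule major basic protein, rose by 4.37 ± 0.90. Awat1, an acyltransferase of wax ester synthesis, was at least 13.1-fold higher, Slc7a11, the cystine transporter, at least 3.29-fold and Cd200r2 at least 5.62-fold. The falls it took in were Alox15, a lipoxygenase of macrophages and eosinophils, at least 3.22-fold lower, Angpt4, an angiopoietin, at least 1.94-fold lower, and Prdm8 (-3.07 ± 0.37), Bex2 (-3.05 ± 0.40), Wfdc16 (-2.81 ± 0.27), Rprml (-2.68 ± 0.40), Hes2 (-2.66 ± 0.29), Fabp1 (-2.61 ± 0.41), Stbd1 (-2.56 ± 0.39) and Tinag (-2.48 ± 0.39).

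In all, 614 genes rose and 473 fell of 16843 tested (limma, adjusted p under 0.05), 329 and 165 of them by 2-fold or more, and the adjusted p of the genes named as called lay between 0.00897 and 0.0488. The balance turned to more falls with quantile normalization (524 rises and 583 falls) and the deposited values (554 and 651). It did not turn with normexp correction (604 and 550) or median scaling (440 and 321). In 5480 genes (32.54%) the arrays of the groups did not overlap, where chance gives 10%. The 10% is an average for exchangeable arrays, and its spread for genes that vary together was not computed. Here slide and sex differed with the groups and could also separate the arrays. The missing spread limits this share in the other comparisons too. Counts adjusted over the list alone were 11 rises for macrophages, 7 for neutrophils, 19 rises and 3 falls for chemokines, 14 rises and 1 fall for senescence, 10 rises for p53 targets, 5 for transitional epithelium and 5 for interferon, and 4 falls for fibroblasts and 4 for smooth muscle.

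Slide 1 held no 9-month cre array and slide 2 held no control array, so no within-slide value exists for this comparison. The slide block joined them through the 3-month cre arrays, of which only 1 was on slide 1. With it the 1087 called genes all kept their sign at a median 0.838 of their log2 fold change, the SE was 1.87 times wider, and 0 genes were called in limma (837 at unadjusted p under 0.05). Blocked list medians were 0.65 for macrophages, 1.60 for neutrophils, 1.91 for chemokines, 1.17 for senescence, 0.32 for p53 targets, 0.34 for transitional epithelium, 0.93 for proliferation, -0.52 for fibroblasts, -0.37 for smooth muscle, -0.41 for alveolar type 1 cells, 0.088 for interferon, 0.057 for immediate early genes and 0.51, a reversed sign, for heart muscle. The slide block ended the calls of the interferon list (adjusted p = 0.0536) and the immediate early list (adjusted p = 0.861) and called the alveolar type 2 list, at -0.27. Animal sex as a covariate also left 0 calls (3710 at unadjusted p under 0.05), and with it the lists of proliferation (0.77, adjusted p = 0.0554), interferon (0.36, adjusted p = 0.142) and alveolar type 1 cells (-0.25, adjusted p = 0.117) were not called. The alveolar type 1 list was also lost with either other filter of dim probes or with 2 groups alone (each -0.39). Without 1 array the counts of rises and falls ranged from 91 and 67, without control replicate 2, to 980 and 658, without 9-month cre replicate 2. Without 9-month cre replicate 3 the interferon median was 0.060, the proliferation median 0.16 and the immediate early median 0.43, and none of these lists was called. The neutrophil median was 1.07 without control replicate 2, the fibroblast and smooth muscle medians -0.38 and -0.33 without control replicate 3 and the senescence median 0.82 without 9-month cre replicate 3, all still called. Interferon was also not called without control replicate 1 (0.27), immediate early genes without control replicate 2 (0.36), and alveolar type 1 markers without control replicate 1 or 2, 3-month cre replicate 1 or 3, or 9-month cre replicate 1 or 3 (-0.41 to -0.14).

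**Figure D2:**
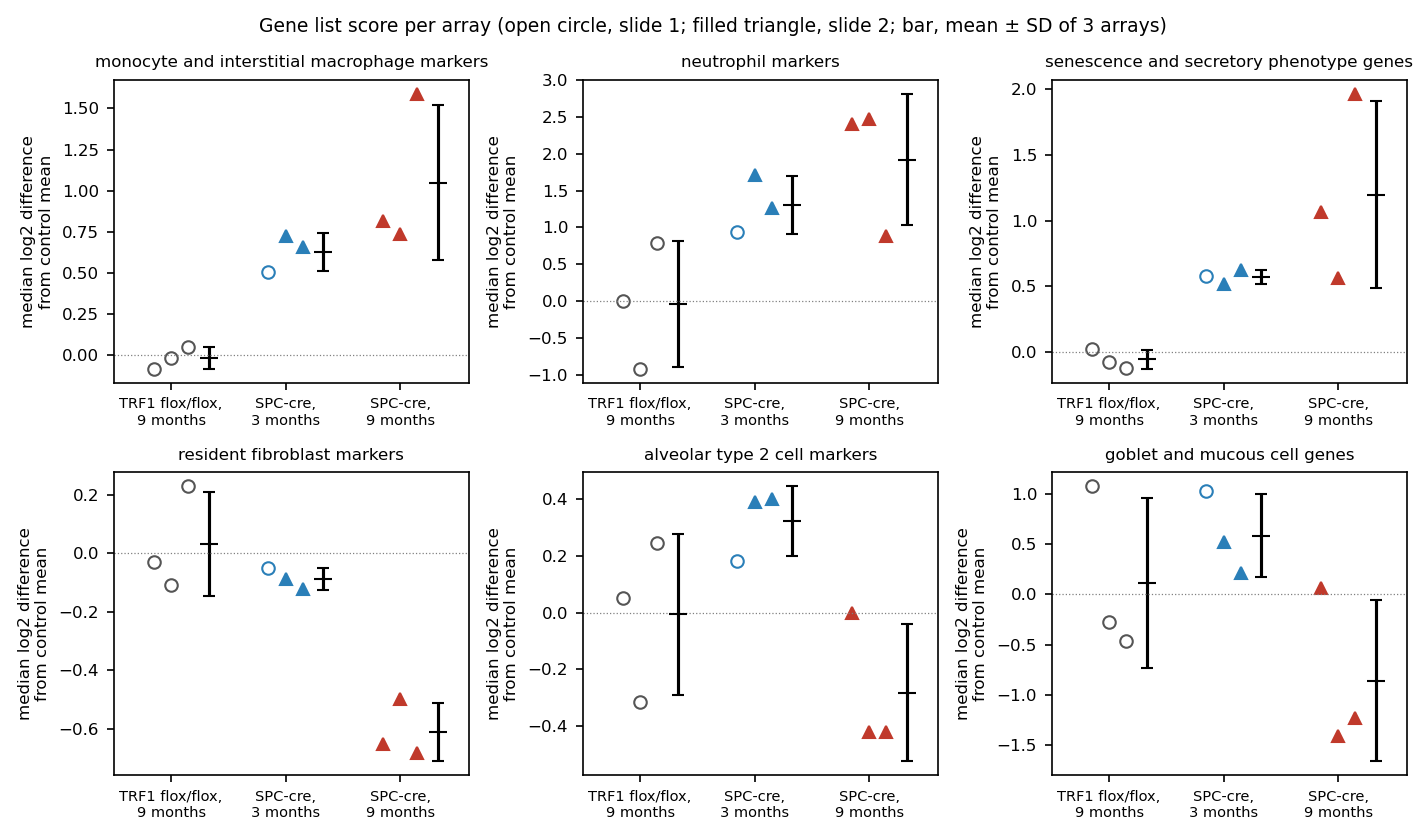
Score of 6 gene lists on each of the 9 arrays, the median over members of the log2 difference from the control mean (y axis), by group (x axis), with open circles for slide 1, filled triangles for slide 2 and bars for the mean ± SD of 3 arrays. The macrophage score was 0.50 to 0.72 on the 3-month cre arrays and 0.74 to 1.59 on the 9-month cre arrays, and the fibroblast score was -0.68 to -0.50 on the 9-month cre arrays.

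The comparison of 3-month cre with control lungs asked which genes differed at the early collection. The controls were 6 months older and had received tamoxifen for 6 more months, so that genotype, age and exposure differed together. Alveolar macrophage markers were higher, with a median log2 fold change of 0.87 (adjusted p = 1.31e-04, and adjusted p = 0.760 with an estimated correlation). Of 18 members 3 rose and 0 fell, Ctsk, a lysosomal cysteine protease, by 2.51 ± 0.28 (SE, n = 3 against 3), Atp6v0d2, a proton pump subunit, by 1.66 ± 0.22, and Mrc1, the mannose receptor, by 1.19 ± 0.15. In the monocyte and interstitial macrophage list 2 of 21 rose, Gpnmb by 2.40 ± 0.24 and Trem2 by 1.84 ± 0.28, with a median of 0.60 (adjusted p = 9.5e-05, and adjusted p = 0.760 with an estimated correlation). Lcn2 rose by 2.12 ± 0.26 and Lgals3 by 0.87 ± 0.13, the 2 called of 17 transitional epithelium genes (median 0.26, adjusted p = 0.0419, and adjusted p = 0.760 with an estimated correlation). Lcn2 was also the 1 called of 15 neutrophil markers, whose median was 1.30 (adjusted p = 0.00125, and adjusted p = 0.760 with an estimated correlation). Gdf15 rose by 2.05 ± 0.29 and was with Gpnmb the 2 called of 25 senescence genes, whose median was 0.57, or 0.50 with members below background set to their bound (adjusted p = 0.00414, and adjusted p = 0.760 with an estimated correlation). Heart muscle genes were lower in the same lungs, with a median of -1.52 and 0 of 15 called in limma (adjusted p = 6.1e-07, and adjusted p = 0.760 with an estimated correlation), 11 being lower at unadjusted p under 0.05.

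Ccl6, a chemokine of the myeloid lineage, rose by 1.95 ± 0.31 and was the 1 called of 28 chemokines and cytokines, with a list median of 1.07, or 0.94 with bounded members (adjusted p = 0.00125, and adjusted p = 0.760 with an estimated correlation). The list of alveolar type 2 markers had a median of 0.35, or 0.37 with bounded members (adjusted p = 0.0122, and adjusted p = 0.760 with an estimated correlation). Of its 21 members 0 were called in limma, with 5 at unadjusted p under 0.05, and the phosphate transporter Slc34a2 was at 0.99 ± 0.25 and Chil1 at 0.97 ± 0.26. Proliferation genes had a median of 0.77 (adjusted p = 0.00125, and adjusted p = 0.760 with an estimated correlation), with 0 of 29 called in limma, 3 at unadjusted p under 0.05 and Cdk1 at 1.88 ± 0.72. Other large rises were Npy, a neuropeptide, at least 4.93-fold higher (adjusted p = 0.0021), Awat1 at least 15.9-fold, Cd200r2 at least 5.03-fold, Stra6l (2.96 ± 0.30), Ren1, the enzyme renin (2.75 ± 0.26), Fgl1, a fibrinogen-like protein (2.66 ± 0.31), Cd200r4 (2.50 ± 0.28) and Speer4a (2.42 ± 0.39). The genes that fell included Klra8 (-1.76 ± 0.24) and Klrb1c (-1.21 ± 0.14), receptors of natural killer cells, and H60c (-0.98 ± 0.13), a ligand of a natural killer cell receptor. Further falls included Smoc2 (-0.99 ± 0.16), Inha (-0.97 ± 0.12), Meis2 (-0.84 ± 0.13), Sfswap (-0.82 ± 0.12), Plppr2 (-0.68 ± 0.11) and Tdrd9, which was below background in the 3-month cre lungs. A further Meis2 probe stood at 0.15 and was not called.

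In total 62 genes rose and 14 fell (limma), 48 and 4 of them by 2-fold or more, and the arrays did not overlap in 5222 genes (31.0%, chance 10%). Counts adjusted over the list alone were 8 rises for monocytes and interstitial macrophages, 10 rises and 1 fall for alveolar macrophages, 5 rises for neutrophils, 2 for chemokines, 6 rises and 1 fall for senescence, 3 rises for alveolar type 2 cells and 3 for transitional epithelium. Adjusted over the list alone, 8 heart muscle genes fell. Sex-linked genes had a median of -4.59 (adjusted p = 0.0171, and adjusted p = 0.760 with an estimated correlation), and all 3 controls read as male.

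Within slide 1, where 1 cre array stood against 3 controls, the medians were 0.50 for monocytes and interstitial macrophages, 0.61 for alveolar macrophages, 0.93 for neutrophils, 1.06 for chemokines, 0.58 for senescence, 0.22 for alveolar type 2 cells, 0.22 for transitional epithelium and -0.67 for heart muscle, and slide 2 held no control. The alveolar type 2 list was not called within slide 1 (adjusted p = 0.149), with the slide block (0.18, adjusted p = 0.189), with quantile normalization or with the deposited values (each 0.19). The last 2 settings also ended the call of transitional epithelium (each 0.085). Within slide 1 and with the slide block the 76 called genes kept their sign, at a median 0.947 of their fold change, and the slide block called 0 genes in limma (1144 at unadjusted p under 0.05). Sex as a covariate called 0 genes (2190 at unadjusted p under 0.05), and with it the proliferation list (0.69, adjusted p = 0.0546) and the sex-linked list (-0.27) were not called. With slide and sex together proliferation (0.53, adjusted p = 0.280) and heart muscle (-0.24) were not called. The counts of rises and falls were 16 and 0 without control replicate 1 (2159 at unadjusted p under 0.05), and 1 and 0 without control replicate 2 (1988) or 3-month cre replicate 2 (1866) or 3 (2407). Without control replicate 3 there were 29 falls. Without 9-month cre replicate 3, which enters only through the shared variance, the counts were 240 and 82. The alveolar type 2 list was not called without control replicate 2 (median 0.23), nor proliferation without control replicate 3 (median 0.62). The neutrophil list kept its call without control replicate 2, at 0.63. Transitional epithelium was not called without control replicate 2 (0.25) or 3 (0.23) or 3-month cre replicate 1 (0.26) or 2 (0.17), and sex-linked genes without control replicate 3 (-4.59) or 3-month cre replicate 1 (-3.58) or 3 (-3.44).

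The comparison of 9-month with 3-month cre lungs asked what changed between early and late collections of the same genotype, with age and duration of tamoxifen moving together. Alveolar type 2 markers fell as a group, with a median log2 fold change of -0.58 (adjusted p = 0.00201, and adjusted p = 0.915 with an estimated correlation). Of 21 members 4 fell and 0 rose, Slc34a2, the sodium-phosphate cotransporter of these cells, by 1.99 ± 0.25 (SE, n = 3 against 3), the calcium-binding S100g by 1.01 ± 0.23, Etv5 by 0.91 ± 0.16 and the mucin Muc1 by 0.79 ± 0.18. Sftpc stood at 0.20 ± 0.16 (adjusted p = 0.455). Goblet and mucous cell genes had a median of -1.47 (adjusted p = 0.0269, and adjusted p = 0.915 with an estimated correlation), and 1 of 13 fell, Tff2, a trefoil peptide of mucous cells, by 2.25 ± 0.26. Resident fibroblast markers had a median of -0.49 (adjusted p = 0.0321, and adjusted p = 0.915 with an estimated correlation). Of 18 members 5 fell, including Npnt by 1.14 ± 0.26, the carboxylesterase Ces1d by 1.13 ± 0.20, Meox2 by 0.81 ± 0.18 and Col13a1 by 0.81 ± 0.16. Cldn18, a tight junction protein of alveolar type 1 cells, fell by 0.78 ± 0.16, the 1 called of 15 markers of those cells.

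Cdkn1a rose by 1.49 ± 0.32, Pmaip1 by 0.93 ± 0.14 and the costimulatory ligand Cd80 by 0.86 ± 0.18, the 3 called of 26 p53 targets, a list with a median of 0.28 (adjusted p = 0.0868). A further Cdkn1a probe stood at 0.27 and was not called. Of 25 senescence genes Cdkn1a rose and the adhesion molecule Icam1 fell by 0.90 ± 0.18 (list median 0.53, adjusted p = 0.0868). Mpo rose by 1.94 ± 0.44 and Oas2 by 1.55 ± 0.18. Further rises were Clec4e, a myeloid pattern receptor (2.83 ± 0.58), Mefv, the inflammasome protein pyrin (2.77 ± 0.39, its other probe 1.59), Apoc2, an apolipoprotein (2.67 ± 0.26), Pla2g7, a lipoprotein-associated phospholipase (2.37 ± 0.36), Cd163l1 (2.52 ± 0.50), Bean1 (2.93 ± 0.59), Catsperz (2.44 ± 0.56) and Pla1a (2.35 ± 0.29). Tdrd9 was at least 2.05-fold higher and Capns2 at least 1.49-fold higher. Alox15 was at least 3.38-fold lower and Angpt4 at least 1.42-fold lower. Arg1, the arginase of alternatively activated macrophages, fell by 2.81 ± 0.59 and was the 1 called of 21 monocyte and interstitial macrophage markers. That list leaned the other way, with 5 members higher and 1 lower at unadjusted p under 0.05 in limma. Its median was 0.15 to 0.35 under other settings, and the list was not called in the main fit. Rprml (-2.81 ± 0.40), Cldn22 (-2.68 ± 0.60), Gsg1l (-2.22 ± 0.47), Reg3g, an antimicrobial lectin (-2.22 ± 0.44), Egfl6 (-2.21 ± 0.35) and Angptl2 (-2.17 ± 0.35) fell as well.

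Here 301 genes rose and 539 fell (limma), 112 and 195 of them by 2-fold or more, and the arrays did not overlap in 5666 genes (33.64%, chance 10%). Adjusted over the list alone, 8 alveolar type 2 markers, 2 goblet cell genes and 6 fibroblast markers fell. Within slide 2, with 3 arrays against 2, the medians were -0.58 for alveolar type 2, -1.16 for goblet and -0.52 for fibroblast markers. All 840 called genes kept their sign at a median 0.962 of their fold change, and 0 genes were called in limma (2975 at unadjusted p under 0.05). The slide block over all 9 arrays also left 0 calls (3589 at unadjusted p under 0.05), and sex as a covariate left 92 rises and 142 falls. The counts of rises and falls were 0 and 0 without 3-month cre replicate 1 (3589 at unadjusted p under 0.05), 1 and 0 without 3-month cre replicate 2 (3461) and 52 and 97 without 3-month cre replicate 3. They were 24 and 43 without 9-month cre replicate 1 and 560 and 560 without 9-month cre replicate 2. The fibroblast call was lost without 3-month cre replicate 3 (median -0.43) and kept without 9-month cre replicate 1 (-0.30), and the goblet call was lost without 9-month cre replicate 3 (median -1.25). Slide with sex ended both (-0.58 and -1.04), and averaging probes ended the fibroblast call (-0.33).

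Both cre groups were set against the same 3 control arrays. Of the genes called, 43 rose and 6 fell in both comparisons and 0 moved in opposite directions. Gpnmb, Gdf15, Lcn2, Trem2, Ctsk, Awat1, Npy, Ren1, Stra6l and Fgl1 were among the shared rises, and Klra8, Klrb1c, H60c, Smoc2 and BC025920 were among the shared falls. BC025920 falls outside the rule for named genes and was chosen after its values were seen. Independent lists of these sizes would share 2.26 rises and 0.393 falls. In 100 simulations with unchanged cre groups set against the same controls the shared count was 0, which says nothing on shared controls, since unchanged groups give too few calls to overlap. With 3 arrays the controls could not be split, and part of the shared calls may come from them. The covariance of the log2 fold changes across genes was 0.141, against a simulated mean of 0.0352 (range -0.0273 to 0.209), so the shared controls alone gave values up to and above the observed one. The correlation across genes was 0.544 against a simulated mean of 0.456, genes not being independent replicates. Same signs were seen in 63.4% of genes against 65.9%. Without 1 array the shared counts ranged from 1 and 0, as without control replicate 2, to 116 and 23 without 9-month cre replicate 3.

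**Figure D3:**
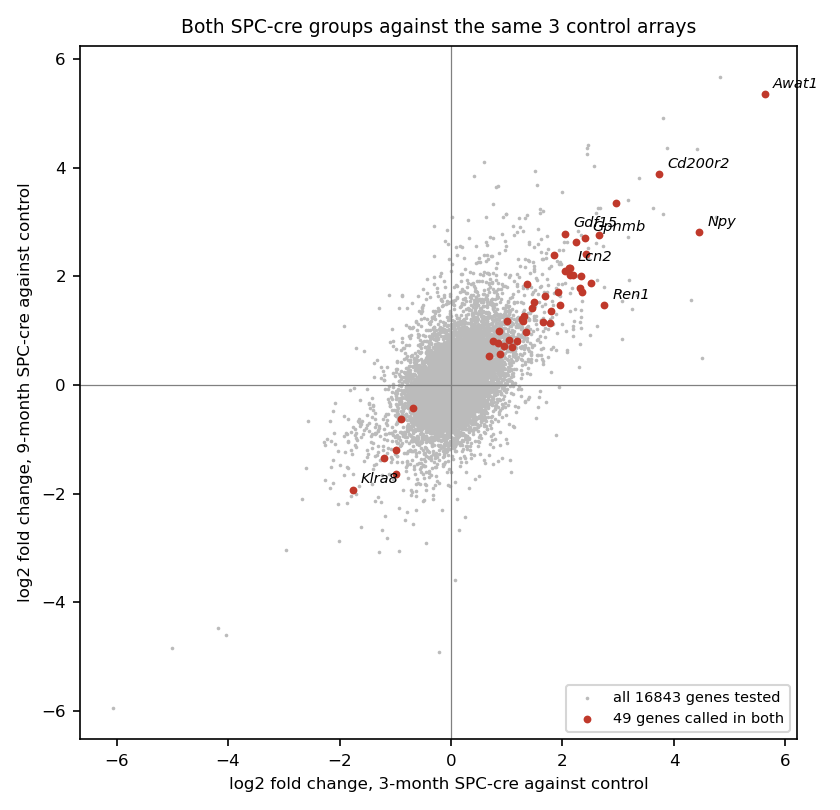
Log2 fold change of each of 16843 genes in 3-month cre (x axis) and 9-month cre (y axis) lungs, both against the same 3 control arrays, with the 49 genes called in both in red. Gpnmb was at 2.40 and 2.71, Gdf15 at 2.05 and 2.78, Npy at 4.45 and 2.81 in fitted values, and Klra8 at -1.76 and -1.93.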

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

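The fits with slide or sex and the regrouping of arrays were planned, while the ratios read from these fits and the tests within 1 slide and of cell composition were chosen only after the results were seen. Groups of 3 arrays are too small to single out 1 array as distant from the rest, so none was tested for that. On the third principal component 9-month cre replicate 3 stood at -43.3, against 17.7 and 31.2 for replicates 1 and 2. Its proliferation score was 2.36 against 0.37 and -0.044, and its interferon score 0.88 against 0.074 and -0.050. Its neutrophil score was lower, at 0.89 against 2.40 and 2.48. The 9-month medians of the proliferation and interferon lists therefore lean on this array. It also scored highest on chemokines (2.8 against 1.8 and 0.5) and senescence (1.97 against 1.07 and 0.56). The same held for macrophages (1.59 against 0.82 and 0.74) and immediate early genes (1.28 against 0.76 and 0.14).

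The rise of macrophage markers in 9-month cre lungs was weighed against 2 other accounts, cell composition and slide. If only epithelial cells had been lost, fibroblast and macrophage markers would gain alike, but the fibroblast score minus the macrophage score was -1.66 (SD 0.54 over 3 arrays), with macrophages at 1.05 and fibroblasts at -0.61. Both list results were known when this test was chosen. Within that limit, a lower share of epithelial cells alone does not account for the rise. Slide cannot be told apart from it, because no control shared a slide with a 9-month cre lung. The 1 3-month cre array on the slide of the controls had a macrophage median of 0.50, in which sex, age and exposure also differed, so a part played by slide may remain.

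The fall of alveolar type 2 markers from 3 to 9 months in cre lungs held within slide 2, with a median of -0.58 in 3 against 2 arrays, so the slide does not account for it. A lower share of these cells alone would lower the surfactant genes alike, yet Sftpa1, Sftpb, Sftpc and Sftpd averaged 0.079 (SE 0.22), more than 2 SE above the -0.58 of the list. That average includes 3-month cre replicate 1 on slide 1, where the mean level of these genes was 7.001. On slide 2 the levels were 7.526 and 7.597 at 3 months, and 7.653, 7.455 and 7.252 at 9 months. Slide may therefore have raised the average. Over both slides these genes did not fall as far as the list, but their change within slide 2 was not tested. A smaller loss of alveolar type 2 cells remains possible within the SE of 0.22. It cannot be told apart from a change of state within these cells, and either could take part in the pattern.

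The number of genes called between 9-month cre and control lungs, 1087, fell to 0 in limma with the slide as a block, although the log2 fold changes kept a median ratio of 0.84 (quartiles 0.648 to 0.988) and 837 genes stayed at unadjusted p under 0.05. The estimate rests on 1 cre array of slide 1, so slide and genotype cannot be told apart. Sex as a covariate kept a median ratio of 1.04 (quartiles 0.960 to 1.12) and also ended the calls, as the SE grew 1.28 times. No control read as female, so the sex effect in that fit rests on 1 male and 2 female arrays in each cre group. A sex effect of the size seen within the cre groups did not account for the fold changes of the called genes as a set. Whether sex acts otherwise in controls could not be tested.

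Regrouping 6 arrays into 3 and 3 gives 10 splits, of which 1, the real one, called as many genes in each comparison. The real counts were 1087, 76 and 840 and the highest other count was 0 in each, and 10 splits are too few for a share under 0.05.

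Between 9 and 3 months of tamoxifen the change against the shared controls was more positive for 301 genes and more negative for 539. Among genes called against controls, the fitted difference in log2 fold change was -0.65 for H60c, -1.28 for Ren1, -1.43 for Hes2, -1.59 for Cd200r4, -1.65 for Npy and -1.66 for Wfdc16. It was -1.78 for Prdm8, -1.88 for Stbd1, -2.12 for Bex2 and -2.81 for Rprml. Fitted values that rest on a group below background were 3.00 for Tdrd9, known only as at least 2.05-fold higher, -2.46 for Angpt4, at least 1.42-fold lower, and -3.66 for Alox15, at least 3.38-fold lower. The list medians differed by -0.58 for alveolar type 2 markers, -1.47 for goblet and mucous cell genes and -0.49 for resident fibroblast markers.

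Probes without a gene name made up 13278 of the 37647 tested. Of these 220 were higher and 158 lower in 9-month cre lungs than in controls, 31 and 49 in 3-month cre lungs than in controls, and 569 and 202 in 9-month than in 3-month cre lungs. The Xist probe, not among the tested genes, stood at -1.33 and -0.95 in 3-month cre replicates 1 and 3 and at -0.99 and -0.71 in 9-month cre replicates 2 and 3, relative to the array 75th percentile.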

How the results depend on the processing

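The called genes kept their direction in most fits, while the number of calls changed. The alternatives were chosen with the design, except slide with sex, the fits within 1 slide and the fit without sex-linked genes, which are tests chosen only after the results were seen. Under every alternative the called genes kept their sign at 9 months (1087 of 1087), at 3 months (76 of 76) and between the cre groups (840 of 840), with few exceptions. These were the mean of a gene's probes (1086 of 1087 and 832 of 840) and slide with sex (1081 of 1087), and the strict filter compared only 975, 58 and 787 of them. Without each array in turn all 1087, 76 and 840 kept their sign. Part of this was fixed in advance, since leaving out an array of the group not compared does not alter a fold change. The same holds for settings that change only the variance or the set of genes tested. The called genes were also chosen for their change in these same arrays, so kept signs are weak evidence of robustness. Of 3392 values of named genes under other settings, 2510 stayed on their side of the threshold, 827 no longer passed, 54 newly passed and 1 reversed. Of 1935 values without 1 array, 1328 stayed, 580 no longer passed, 27 newly passed and 0 reversed. Other settings included fits to 2 groups alone and, outside the 9-month comparison with controls, fits within 1 slide. Under these settings Terf1 ranged from -0.58 to -0.29 at 9 months (adjusted p 0.105 to 0.985), from -0.56 to -0.37 at 3 months and from -0.027 to 0.083 between the cre groups. Without 1 array Terf1 ranged from -0.66 to -0.33, from -0.70 to -0.42 and from -0.064 to 0.23. Low signal over background limits the fold changes of dim genes, and 6 residual degrees of freedom limit every test.

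At the preset correlation between genes, several lists were called under every alternative and without each array in turn, and with an estimated correlation 0 lists were called in any comparison. Medians of log2 fold changes are given as the range under alternatives, then the range without 1 array. At 9 months against controls the lists were transitional epithelium (0.15 to 0.50, and 0.21 to 0.42), p53 targets (0.29 to 0.49, and 0.28 to 0.40), senescence (1.12 to 1.31, and 0.82 to 1.70) and resident fibroblasts (-0.71 to -0.52, and -0.67 to -0.38). Also called throughout were smooth muscle (-0.68 to -0.36, and -0.81 to -0.33), monocytes and interstitial macrophages (0.65 to 0.99, and 0.67 to 1.03), neutrophils (1.60 to 2.64, and 1.07 to 2.35) and chemokines (1.47 to 1.91, and 1.25 to 2.41). At 3 months the lists were senescence (0.28 to 0.61, and 0.51 to 0.61), alveolar macrophages (0.61 to 1.11, and 0.64 to 1.04), monocytes and interstitial macrophages (0.43 to 0.77, and 0.51 to 0.76), neutrophils (0.93 to 1.90, and 0.63 to 1.73) and chemokines (0.73 to 1.14, and 0.77 to 1.24). Between the cre groups the alveolar type 2 markers kept their call at the preset correlation (-0.65 to -0.43, and -0.80 to -0.48), and the goblet and fibroblast lists did not. For these lists the slide block, the fit within slide 2 and the fit without 3-month cre replicate 1 rest on the same fold changes and count as 1 check.

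For the other results the cause was not tested, and values beside a list name are medians of the log2 fold changes of its members. Against controls the comparisons are named by month, and counts of genes are higher or lower in the cre or later group. Normexp correction gave 38 higher at 3 months and 489 higher between the cre groups, with 28 higher shared. That choice newly called goblet (-0.86), alveolar macrophage (0.51) and sex-linked (-2.32) at 9 months, ciliated (0.27) at 3 months and alveolar type 1 (-0.32) between the cre groups. Quantile normalization newly called alveolar type 2 (-0.44), club (-0.36), endothelial (-0.21) and alveolar macrophage (0.46) at 9 months, alveolar type 1 (-0.38) and club (-0.55) between the cre groups. It ended the calls of alveolar type 2 (0.19) and transitional (0.085) at 3 months. Median scaling gave 7 lower at 3 months and 158 higher and 269 lower between the cre groups, with 3 lower shared. Newly called with it were alveolar macrophage (0.45) and sex-linked (-4.79) at 9 months, dendritic (0.35) at 3 months and alveolar type 1 (-0.41), senescence (0.47), monocyte and macrophage (0.28), chemokine (0.52) and immediate early (0.44) between the cre groups. The deposited values gave 35 higher and 8 lower at 3 months and 452 higher between the cre groups, with 25 higher shared. They newly called alveolar type 2 (-0.49), club (-0.32), endothelial (-0.19) and alveolar macrophage (0.48) at 9 months and ended those of alveolar type 2 (0.19) and transitional (0.085) at 3 months. Under the deposited values 45.98% of the genes called at 9 months were higher, and under quantile normalization 47.34%, against 56.49% with the 75th percentile. The median over all genes stayed between -0.092 and 0.060 under every scaling.

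Testing dim probes too gave 280 higher and 209 lower at 9 months, 13 higher and 1 lower at 3 months and 47 higher and 57 lower between the cre groups, with 10 higher and 1 lower shared. It gave new calls for alveolar macrophage (0.50) at 9 months, ciliated (0.24), goblet (0.48), p53 (0.077), dendritic (0.35), lymphoid tissue (0.16), DNA damage (0.21), unfolded protein (0.29), lipid (0.21) and erythroid (0.99) at 3 months and alveolar type 1 (-0.35), p53 (0.28), senescence (0.53), monocyte and macrophage (0.35) and immediate early (0.50) between the cre groups. It ended calls for alveolar type 1 (-0.39) at 9 months, sex-linked (-4.17) at 3 months. The strict filter gave 34 higher at 3 months, with 25 higher shared. That fit newly called goblet (-0.97) and alveolar macrophage (0.50) at 9 months. It ended the calls of alveolar type 1 (-0.39) at 9 months. Averaging the probes newly called alveolar macrophage (0.50), B cell (-0.71) and sex-linked (-4.55) at 9 months, dendritic (0.41) and unfolded protein (0.34) at 3 months. It ended calls for fibroblast (-0.33) between the cre groups. Of 283 genes called between the cre groups and measured by several probes, 64 had a probe of opposite sign, and in Dnajb6, Slc44a1 and Snph, chosen after their values were seen, that probe was itself called. The numbers were 46 of 354 at 9 months and 1 of 28 at 3 months, with 0 such probes called in limma. Fitting 2 groups alone gave 127 higher and 58 lower at 9 months, 299 higher and 90 lower at 3 months and 113 higher and 222 lower between the cre groups. New calls were erythroid (0.44) and sex-linked (-4.73) at 9 months, ciliated (0.24), smooth muscle (-0.19), dendritic (0.35) and DNA damage (0.18) at 3 months. It ended the calls of alveolar type 1 (-0.39) at 9 months. Trended robust variance gave 523 higher and 822 lower between the cre groups. Weighting the arrays gave 982 higher at 9 months, 2822 higher and 1472 lower at 3 months and 950 higher and 1379 lower between the cre groups, with 491 higher and 169 lower shared. It called Terf1 at 3 months, at -0.53 (adjusted p = 0.0256, against 0.0256 to 0.886 over all alternatives).

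The replicate number as a block, a replicate block, rests on shared numbers alone, since deviations of same-numbered arrays correlated at -0.236 to 0.045 and 1 of 9 arrays correlated best with its own number. The replicate block gave 201 higher and 116 lower at 9 months, 37 higher and 5 lower at 3 months and 2 higher and 4 lower between the cre groups, with 25 higher and 3 lower shared. It newly called goblet (-0.89), alveolar macrophage (0.50), B cell (-0.65) and sex-linked (-4.73) at 9 months, ciliated (0.24) at 3 months and alveolar type 1 (-0.35) between the cre groups.

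The slide block left 0 calls in limma in all 3 comparisons, with 837, 1144 and 3589 genes at unadjusted p under 0.05 at 9 months, at 3 months and between the cre groups, and 0 shared genes. That choice newly called alveolar type 2 (-0.27) and sex-linked (-8.04) at 9 months, ciliated (0.43), lymphoid tissue (0.40), DNA damage (0.25) and lipid (0.25) at 3 months and alveolar type 1 (-0.46) and heart (1.24) between the cre groups. It ended calls for interferon (0.088) and immediate early (0.057) at 9 months, alveolar type 2 (0.18), mesothelial (-0.33), T and NK (0.47) and interferon (0.26) at 3 months. Reversed were heart (0.51) and erythroid (-2.09) at 9 months, erythroid (-0.86) at 3 months. The sex covariate left 0 calls in limma at 9 months (3710 genes at unadjusted p under 0.05) and 0 at 3 months (2190), 92 higher and 142 lower between the cre groups, and 0 shared genes. Newly called with it were alveolar macrophage (0.65), B cell (-0.68) and clock (-0.36) at 9 months, ciliated (0.52), smooth muscle (-0.19) and lipid (0.34) at 3 months. It ended the calls of alveolar type 1 (-0.25), proliferation (0.77) and interferon (0.36) at 9 months, proliferation (0.69), mesothelial (-0.32), T and NK (0.40), interferon (0.42) and sex-linked (-0.27) at 3 months. Slide plus sex left 0 calls in limma in all 3 comparisons, with 950, 990 and 3393 genes at unadjusted p under 0.05, and 0 shared genes. It gave new calls for ciliated (0.70) and alveolar macrophage (0.51) at 9 months, ciliated (0.77), goblet (1.52) and lipid (0.46) at 3 months and heart (1.35) between the cre groups. It ended calls for alveolar type 1 (-0.28), proliferation (0.50), interferon (0.086) and immediate early (0.29) at 9 months, proliferation (0.53), mesothelial (-0.14), interferon (0.12), heart (-0.24) and sex-linked (-0.13) at 3 months and goblet (-1.04) and fibroblast (-0.58) between the cre groups. It reversed heart (1.08) and erythroid (-3.06) at 9 months, matrix (-0.23), T and NK (the test turned down, with a median of 0.22) and erythroid (-1.48) at 3 months. It reversed Reg3g at 9 months, to 0.055 from -2.11.

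Slide 2 alone left 0 calls in limma between the cre groups (2975 genes at unadjusted p under 0.05). That fit newly called alveolar type 1 (-0.46) and heart (1.24) between the cre groups. Slide 2 with sex left 0 calls in limma there (2391 at unadjusted p under 0.05). New calls were alveolar type 1 (-0.47) and heart (1.35) between the cre groups. It turned the direction of the erythroid test to down between the cre groups, where the median went from -0.40 to -1.46 with no change of sign. Slide 1 alone, with 1 cre array assumed to vary like the controls, left 0 higher and 4 lower genes in limma at 3 months (1586 at unadjusted p under 0.05), and the 4 were the Y-linked Ddx3y (-6.08), Eif2s3y (-9.05), Kdm5d (-7.40) and Uty (-5.85), named after their values were seen. It newly called ciliated (0.43), dendritic (0.28), lymphoid tissue (0.40), DNA damage (0.25) and lipid (0.25) at 3 months. It ended the calls of alveolar type 2 (0.22), mesothelial (-0.33) and T and NK (0.47) at 3 months. It reversed erythroid (-0.86) at 3 months. Leaving out the sex-linked genes changed no list call. The 9-month comparison with controls has no fit within 1 slide, since no slide held both groups.

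Without control 1 the counts were 193 higher and 158 lower at 9 months, 16 higher and 0 lower at 3 months (2159 at unadjusted p under 0.05 in limma) and 142 higher and 246 lower between the cre groups, with 12 higher and 0 lower shared. That choice newly called skeletal muscle (-0.48) and adipocyte (-1.04) at 9 months and goblet (1.09), smooth muscle (-0.29), dendritic (0.46), skeletal muscle (-0.19) and adipocyte (-0.66) at 3 months. That fit lost the calls of alveolar type 1 (-0.39) and interferon (0.27) at 9 months. Without control 2 counts were 91 higher and 67 lower at 9 months, 1 higher and 0 lower at 3 months (1988 at unadjusted p under 0.05 in limma) and 70 higher and 97 lower between the cre groups, with 1 higher and 0 lower shared. The new calls were alveolar type 2 (-0.50) and goblet (-0.98) at 9 months and ciliated (0.39) at 3 months. The calls lost were alveolar type 1 (-0.36) and immediate early (0.36) at 9 months and alveolar type 2 (0.23), transitional (0.25), mesothelial (-0.32) and T and NK (0.36) at 3 months. Without control 3 the counts were 200 higher and 120 lower at 9 months, 29 lower at 3 months and 779 lower between the cre groups, with 15 lower shared. Newly called were goblet (-0.98), matrix (0.38), alveolar macrophage (0.65), B cell (-0.73), clock (-0.70) and sex-linked (-4.66) at 9 months. Calls ended for transitional (0.23), proliferation (0.62), mesothelial (-0.47), T and NK (0.45), interferon (0.42) and sex-linked (-4.59) at 3 months.

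Without 3-month cre 1 counts were 0 higher and 0 lower between the cre groups in limma (3589 at unadjusted p under 0.05). That fit added B cell (-0.65) at 9 months, adipocyte (-0.74) and erythroid (1.73) at 3 months and alveolar type 1 (-0.46) and heart (1.24) between the cre groups. That fit ended alveolar type 1 (-0.39) at 9 months and transitional (0.26) and sex-linked (-3.58) at 3 months. Without 3-month cre 2 the counts were 269 higher and 198 lower at 9 months, 1 higher and 0 lower at 3 months (1866 at unadjusted p under 0.05 in limma) and 1 higher and 0 lower between the cre groups (3461), with 1 higher and 0 lower shared. Newly called lists were sex-linked (-4.73) at 9 months, unfolded protein (0.36) at 3 months and immediate early (0.70) between the cre groups. Lost calls were transitional (0.17) and interferon (0.26) at 3 months. Without 3-month cre 3 counts were 393 higher at 9 months, 1 higher and 0 lower at 3 months (2407 at unadjusted p under 0.05 in limma) and 52 higher and 97 lower between the cre groups, with 1 higher and 0 lower shared. That fit newly called ciliated (0.38) and smooth muscle (-0.25) at 3 months. That fit ended alveolar type 1 (-0.39) at 9 months, mesothelial (-0.26), T and NK (0.45) and sex-linked (-3.44) at 3 months and fibroblast (-0.43) between the cre groups.

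Without 9-month cre 1 the counts were 148 higher and 108 lower at 9 months and 24 higher and 43 lower between the cre groups. That fit added alveolar type 2 (-0.46), goblet (-1.34) and sex-linked (-6.85) at 9 months and club (-0.52), alveolar macrophage (-0.53), monocyte and macrophage (0.47) and lipid (-0.38) between the cre groups. No longer called was alveolar type 1 (-0.41) at 9 months. Without 9-month cre 2 counts were 980 higher and 658 lower at 9 months and 560 higher between the cre groups, with 65 higher shared. Added calls were club (-0.53), endothelial (-0.20), mesothelial (-0.46), alveolar macrophage (0.66), B cell (-0.91) and clock (-0.42) at 9 months, dendritic (0.35) at 3 months and alveolar type 1 (-0.55), club (-0.55), p53 (0.36), senescence (0.59), proliferation (0.49), monocyte and macrophage (0.40), chemokine (1.12) and immediate early (0.74) between the cre groups. Without 9-month cre 3 the counts were 240 higher and 82 lower at 3 months, with 116 higher and 23 lower shared. The lists gained were ciliated (0.58) and endothelial (-0.21) at 9 months, ciliated (0.24), smooth muscle (-0.19) and dendritic (0.35) at 3 months and dendritic (-0.48), T and NK (-0.36), neutrophil (1.44) and DNA damage (-0.26) between the cre groups. The lists lost were alveolar type 1 (-0.14), proliferation (0.16), interferon (0.060) and immediate early (0.43) at 9 months and goblet (-1.25) between the cre groups. It reversed proliferation (-0.64) between the cre groups.

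Over the 9 fits without 1 array, the medians of lists whose call changed had these ranges. At 9 months they were alveolar type 2 (-0.50 to -0.11), alveolar type 1 (-0.53 to -0.14), club (-0.53 to 0.16), ciliated (0.093 to 0.58), goblet (-1.34 to -0.34), proliferation (0.16 to 1.38), matrix (-0.062 to 0.38), endothelial (-0.21 to -0.080), mesothelial (-0.46 to -0.042), alveolar macrophage (0.31 to 0.66), B cell (-0.91 to -0.49), interferon (0.060 to 0.49), clock (-0.70 to -0.10), immediate early (0.36 to 0.99), skeletal muscle (-0.48 to 0.061), adipocyte (-1.04 to -0.092) and sex-linked (-6.85 to -3.58). At 3 months they were alveolar type 2 (0.23 to 0.46), ciliated (0.24 to 0.39), goblet (0.19 to 1.09), transitional (0.17 to 0.29), proliferation (0.62 to 0.93), smooth muscle (-0.29 to -0.0090), mesothelial (-0.50 to -0.26), dendritic (0.20 to 0.46), T and NK (0.36 to 0.69), interferon (0.26 to 0.42), unfolded protein (0.19 to 0.37), skeletal muscle (-0.19 to 0.071), adipocyte (-0.74 to 0.081), erythroid (0.011 to 1.73) and sex-linked (-6.83 to -3.44). Between the cre groups they were alveolar type 1 (-0.55 to -0.21), club (-0.55 to -0.021), goblet (-1.73 to -1.16), p53 (0.11 to 0.36), senescence (0.19 to 0.59), proliferation (-0.64 to 0.49), fibroblast (-0.67 to -0.30), alveolar macrophage (-0.53 to -0.29), monocyte and macrophage (0.15 to 0.47), dendritic (-0.48 to 0.015), T and NK (-0.36 to -0.12), neutrophil (0.13 to 1.44), chemokine (0.18 to 1.12), DNA damage (-0.26 to -0.029), lipid (-0.38 to -0.13), immediate early (0.20 to 0.74) and heart (0.23 to 1.24). Some called lists kept their call while the median moved by over 1.5 times. At 9 months these were neutrophil (1.07) without control 2, fibroblast (-0.38) and smooth muscle (-0.33) without control 3 and heart without control 1 (-1.32) or control 3 (-0.46). Transitional moved to 0.21 without 9-month cre 1, interferon to 0.49 and immediate early to 0.99 without 9-month cre 2, and senescence to 0.82 and smooth muscle and pericyte markers to -0.36 without 9-month cre 3. At 3 months neutrophil moved to 0.63 without control 2, and between the cre groups fibroblast moved to -0.30 without 9-month cre 1.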

Other observations

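The values that follow come from gene lists fixed with the design, and only the fits within slide 1 and with slide and sex together were chosen after the results were seen. Members that did not pass the test are given as log2 fold changes.

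Single genes of the body clock changed, while their list was not called in any comparison. In 9-month cre lungs against controls 3 of 15 fell, the repressors Nr1d1 (-1.84 ± 0.22) and Nr1d2 (-1.19 ± 0.18) and the output factor Dbp (-1.87 ± 0.41), and Nfil3, which opposes Dbp, rose by 1.76 ± 0.24. The same 3 fell against 3-month cre lungs, by 1.39 ± 0.22, 1.12 ± 0.18 and 1.85 ± 0.41. The list medians were -0.24 (adjusted p = 0.0796) and -0.39 (adjusted p = 0.166), and 0 members were called in limma at 3 months, with 2 at unadjusted p under 0.05 (median 0.014). The hour of collection is not given in the sources used here.

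In the T and natural killer cell list 2 of 26 members were called higher and 3 lower at 9 months. Against controls, 9-month cre lungs had higher Foxp3, the factor of regulatory T cells (1.65 ± 0.37), and Ctla4 was at least 2.08-fold higher. The 3 lower members were Ncr1 (-2.41 ± 0.46), Gzma (-1.47 ± 0.35) and Klrb1c (-1.34 ± 0.14), genes expressed in natural killer cells. The list median was 0.23 at 9 months (adjusted p = 0.535) and -0.21 between the cre groups. At 3 months it was 0.51 (adjusted p = 0.0319, and adjusted p = 0.760 with an estimated correlation), or 0.47 with bounded members, and 1 of 26 members, Klrb1c, fell. That call was lost with the slide block (0.47, adjusted p = 0.0756), within slide 1 (0.47, adjusted p = 0.141), with the sex covariate (0.40, adjusted p = 0.357) and without control replicate 2 (0.36) or 3 (0.45) or 3-month cre replicate 3 (0.45). With slide and sex together the direction of the list test turned down, but the list was not called (adjusted p = 0.694) and its median stayed at 0.22. Cxcl13, a B cell attractant of lymphoid follicles, rose by 2.53 ± 0.33 and Fcamr by 1.69 ± 0.35 at 9 months, 2 of 12 lymphoid tissue genes (median 0.090, adjusted p = 0.462). Fcer2a, a receptor of B cells, fell by 1.62 ± 0.26 against controls and by 1.23 ± 0.26 against 3-month cre lungs, where the B cell list had medians of -0.65 and -0.27. Flt3, a receptor of dendritic cell precursors, rose by 1.05 ± 0.13 at 9 months and H2-Ob fell by 0.85 ± 0.13. The class II genes H2-Aa (-1.34 ± 0.30) and H2-DMa (-1.19 ± 0.26) fell from 3 to 9 months in cre lungs, with a dendritic cell list median of -0.24. Prg2 and Alox15 were the 2 called of 14 mast cell, basophil and eosinophil markers at 9 months, and Fcer1a fell by 0.75 ± 0.17 from 3 to 9 months in cre lungs.

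Endothelial and epithelial genes outside the alveolus showed single changes. Kdr, a receptor for vascular growth factor, fell by 0.96 ± 0.16 at 9 months against controls, and Apln (-1.88 ± 0.43), Ednrb (-1.43 ± 0.28) and Car4 (-0.91 ± 0.19), the latter 2 described in alveolar capillaries, fell from 3 to 9 months in cre lungs, with list medians of -0.16 and -0.090. The other probes of Ednrb were at -0.37 and -1.88. Reg3g and Upk3a, 2 of 16 club cell genes, fell at 9 months against controls by 2.11 ± 0.44 and 1.93 ± 0.42, and with the slide as a block Reg3g stood at -0.57. The club cell list medians were -0.25 at 9 months (adjusted p = 0.161) and -0.39 between the cre groups. Bpifb1 (-1.54 ± 0.36) and Tff2 (-1.34 ± 0.26) fell among 13 goblet cell genes at 9 months (median -0.89, adjusted p = 0.0612), and their slide-blocked list median was -0.25. Normexp correction (-0.86) and the strict filter (-0.97) called the goblet list. Alveolar macrophage markers had a median of 0.50 at 9 months (adjusted p = 0.0612). That list lay near the threshold, and 10 of 15 other settings called it, among them quantile normalization (0.46), the deposited values (0.48) and the sex covariate (0.65). Ctsk (1.87 ± 0.28), Atp6v0d2 (1.15 ± 0.22), Mrc1 (0.81 ± 0.15) and Spp1 rose and Fabp1 fell, and between the cre groups the median was -0.38.

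Other pathways held few calls. Ten1, a subunit of the complex that caps telomere ends, fell by 1.10 ± 0.25 from 3 to 9 months in cre lungs (telomere list median 0.031), and 0 of 20 telomere genes were called in limma at 3 months, with 2 higher and 5 lower at unadjusted p under 0.05 (median 0.079). Dnajb9 fell by 0.77 ± 0.16 (its other probe -0.21) among 17 unfolded protein response genes (median 0.13) and the chemokine Ccl11, an eosinophil attractant, by 0.69 ± 0.15 (list median 0.58) between the same groups. Gpam, an enzyme of glycerolipid synthesis, fell by 0.69 ± 0.12 at 9 months against controls, with its other probe at 0.0092, and the lipid list medians were -0.031 at 9 months and 0.21 at 3 months. DNA damage genes had medians of 0.12 at 9 months and 0.19 at 3 months, and 0 of 19 were called in limma in either. At unadjusted p under 0.05, 2 were higher and 3 lower at 9 months, and 4 were higher at 3 months. Ciliated cell markers had medians of 0.27 at 9 months and 0.24 at 3 months (adjusted p = 0.417 and 0.0742), and basal cell genes of -0.17 and 0.25. The ciliated list was called at 3 months in 8 of 16 other settings, among them the slide block (0.43), the sex covariate (0.52) and slide with sex (0.77), and at 9 months with slide and sex (0.70). The slide block also called the lipid (0.25) and DNA damage (0.25) lists at 3 months.

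Other tissues that can be carried over at dissection were measured by lists of their own. At 9 months the medians were -0.25 for skeletal muscle, -0.33 for adipocytes, 0.44 for red cell precursors and -0.042 for thymus, and at 3 months they were 0.047, -0.35, 0.76 and 0.25. With the slide block the red cell (erythroid) list turned to a called fall, at -2.09 (adjusted p = 3.6e-06) and -0.86 (adjusted p = 0.0028), and the adipocyte medians turned to 0.50 and 0.61, not called. Sex-linked genes were at -4.73 at 9 months (adjusted p = 0.0524), called at -8.04 with the slide block, and -0.093 between the cre groups. Mesothelial markers had a median of -0.26 at 9 months and of -0.36 at 3 months, where the list was called (adjusted p = 0.0280, and adjusted p = 0.760 with an estimated correlation), and 0 of 8 members passed in limma, with 1 at unadjusted p under 0.05. It was not called with the slide block or within slide 1 (each -0.33, adjusted p = 0.156), with the sex covariate (-0.32, adjusted p = 0.0787), with slide and sex together (-0.14, adjusted p = 0.654), or without control replicate 2 (-0.32) or 3 (-0.47) or 3-month cre replicate 3 (-0.26). Interferon genes were called as a list at 3 months, with a median of 0.35 (adjusted p = 0.0335, and adjusted p = 0.760 with an estimated correlation) and 0 of 26 members called in limma, with 3 at unadjusted p under 0.05, and were not called without control replicate 3 (0.42) or 3-month cre replicate 2 (0.26). The interferon call was also lost with the slide block (0.26, adjusted p = 0.113), the sex covariate (0.42, adjusted p = 0.154) and slide with sex (0.12, adjusted p = 0.694). Median, mean and direction of the test differed in sign for some uncalled lists. At 9 months these were mast cells, DNA damage, thymus, lipid synthesis and telomere components, and at 3 months skeletal muscle, telomere components, clock genes, B cells and mast cells. Between the cre groups they were interferon, mesothelial, matrix, red cell, mast cell, sex-linked, proliferation and unfolded protein response genes.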
